A study of Xenopus laevis with 6 samples.

How the data were processed

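The series holds EU-labelled RNA from Xenopus laevis embryos in 6 libraries, 2 each for control embryos at 5 hpf, control embryos at 7.5 hpf and embryos in 0.2 mg/ml cycloheximide from 5 to 7.5 hpf. Per the labels' protocols, embryos were injected at the 1-cell stage with 10 nl of 50 mM EU (about 0.5 mM final) and raised at 22 °C. Per the same protocols, labelled RNA was biotinylated by a click reaction, captured on streptavidin beads and made into total-RNA libraries with depletion of ribosomal RNA. The labels give all libraries the same batch, and the series design states that the replicates came from 1 clutch.

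Per the submitters' processing notes, the authors quantified transcripts with Salmon 0.12.0 and normalized with DESeq2. The aligner settings, genome build, annotation and use of strand are not given in the sources used here. The deposited values are treated as a score: gene-level counts that the authors divided by 1 size factor per library and rounded to whole numbers. That reading rests on the values. Each library skips or repeats whole numbers at a regular spacing other than 1 and the totals lie in a narrow range, 6680033 to 7742693. The spacing estimates what 1 read was worth, between 0.446 and 2.31. Because rounding is coarse against that spacing, whole reads were not recovered. In control 7.5 hpf replicate 2 and CHX replicate 1 a neighbouring spacing matched nearly as well (0.686 and 0.685). In control 7.5 hpf replicate 1 a much smaller spacing of 0.351 matched nearly as well as 1.18 (r = 0.834 and 0.845). Depths are therefore estimates, and that library may be deeper than estimated.

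The table held 50489 genes, of which 18221 were at 0 in all libraries and 17497 above 0 in all. It had 1738 entries with a repeated name (482 names), which were kept as separate genes. The analysis plan, gene lists and naming rule were fixed before the data were examined. The plan assumed raw counts and gave limma for any other unit, so limma was the test used. A gene entered the test if its mean value was at least 11.8, which is 10 reads at the mean spacing of 1.18. This left 19195 genes.

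Values were compared as log2(value + 1) with limma 3.58.1 in R 4.3.3, using a linear model of the 3 groups over all 6 libraries and moderated tests with an intensity trend. The fit had 3 residual degrees of freedom and a prior of 7.29. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were control 7.5 hpf against control 5 hpf, CHX against control at 7.5 hpf, and CHX at 7.5 hpf against control 5 hpf. Genes that rose or fell in controls were those called with a log2 fold change of at least 1 in size. Overlaps were set against the product of the list sizes over the genes tested, and against 100 simulated draws of unchanged groups. Each draw gave all 6 libraries independent noise around 1 mean per gene, and its comparisons shared groups as the real ones do. Other tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

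Of 20 gene lists, 19 had measured members: oocyte maternal transcripts, nodal ligands, dorsal organizer, mesoderm, endoderm, ectoderm and neural, BMP, FGF and ERK, Wnt and Notch targets, pluripotency and genome activation factors, immediate early genes, stress response, cell cycle, replication-dependent histones, ribosomal proteins, ribosome biogenesis, RNA polymerase II machinery and splicing factors. The list of mitochondrially encoded genes matched 0 genes tested. Some genes stand on more than 1 list. Lists were tested with camera (preset correlation 0.01, and an estimated correlation) and with fry, adjusted over the lists of a comparison. Members were also adjusted over the list alone.

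Genes were named by rule. For each comparison the rule takes the 8 named genes with the largest change in each direction that were called, had an average log2 CPM of at least 2 and did not overlap between groups. From each list it takes up to 4 called members with the smallest adjusted p and the most abundant member. From the genes that rose in controls it takes the 6 highest and 6 lowest in CHX against control. Not every gene it admits is printed. Genes listed at 0 in every library of the reference group are given as values without a fold change.

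The test was checked on simulated data with 200 genes changed in each of 5 runs of 19195 genes. For controls from 5 to 7.5 hpf it recovered 35.9%, 67.0% and 75.3% of 2-, 4- and 8-fold changes, with 6.26% of calls false. For CHX against control at 7.5 hpf it recovered 37.2%, 68.2% and 77.8%, with 1.60% false. For CHX against 5 hpf it recovered 36.0%, 64.6% and 81.6%, with 6.13% false. The simulated spread was averaged over the groups, and genes were drawn independently. These rates therefore do not cover the wider spread of the 7.5 hpf controls or shifts shared by many genes.

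Alternatives were other scalings (recomputed median of ratios, totals, oocyte transcripts), no filter or a stricter one (a mean of 50 reads), pseudocounts of 0.5 and 5, the replicate number as a block, a fit to the 2 groups compared, another threshold, and leaving out each library. Trimmed-mean scaling, library weights and thinning to the shallowest library were added after seeing the data. Leaving out a library leaves a lone sample in its group, so a call lost there may reflect low power and not a changed difference. Gene names and neighbours were looked up in a reference table of assembly Xenopus_laevis_v10.1, which matched 17122 of the 19195 genes tested. Neighbours were taken in order of start position on the same chromosome.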

Results

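Newly made RNA was profiled in Xenopus laevis embryos around the time the zygotic genome becomes active, with and without protein synthesis. Embryos had received 5-ethynyl uridine (EU), a uridine analogue that is built into new transcripts, at the 1-cell stage, so that labelled RNA could be biotinylated and pulled out of total RNA before sequencing. RNA captured at 7.5 hpf therefore included any made earlier and still present. The series holds 6 libraries in 3 groups of 2: untreated embryos at 5 hours post fertilization (hpf), untreated embryos at 7.5 hpf, and embryos kept in 0.2 mg/ml cycloheximide (CHX), an inhibitor of translation, from 5 to 7.5 hpf. The design allows 3 questions: which transcripts rose or fell over the interval, which differed at 7.5 hpf when translation was blocked, and which still changed from the 5 hpf level in the presence of the inhibitor. Both replicates of every group came from 1 clutch, so each p-value measures the spread between these samples and not between clutches.

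The summed normalized value per library lay between 6680033 and 7742693. From the spacing of the low values, 1 read was worth an estimated 1.85 and 2.31 units in the 5 hpf libraries, 1.18 and 0.648 in the 7.5 hpf controls and 0.649 and 0.446 in the CHX libraries, so the 5 hpf libraries were the shallowest. A low transcript was therefore harder to detect at 5 hpf than later. Replicates correlated across genes with r = 0.921 at 5 hpf, 0.853 in the 7.5 hpf controls and 0.927 under CHX, where genes are not independent replicates. Squared differences between replicates were 5.27, 40.2 and 25.8 times the sampling variance on average, so no pair was 1 library deposited again. The first principal component held 56.2% of the variance and set both 5 hpf libraries (-138 and -135) apart from the other 4, which ran from 31.4 (control 7.5 hpf replicate 2) to 109 (control 7.5 hpf replicate 1). The 7.5 hpf control replicates stood further apart on it than either other pair. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. L and S copies of a gene may share reads, and whether counting used strand is not given in the sources used here.

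From 5 to 7.5 hpf, captured RNA of regulators of every germ layer rose in untreated embryos. Of 19195 genes tested, 1136 were higher and 137 lower at 7.5 hpf (limma, Benjamini-Hochberg adjusted p under 0.05), and 1019 and 53 of these changed at least 2-fold. Many transcripts began from nothing detected: 361 of the genes called higher were listed at 0 in both 5 hpf libraries. The BMP-responsive repressor gene id3.L was listed at 0 at 5 hpf and had normalized values of 1301 and 525 in the 7.5 hpf controls. In the same libraries the forkhead gene foxa4.L reached 1449 and 417, the BMP antagonist chrd.1.S 904 and 355, the zinc finger gene sp5l.L 1515 and 535, and the hyaluronan synthase gene has2.L 984 and 362, each from 0 at 5 hpf. The median log2 fold change of all genes was 0.03 as deposited, 0.21 when libraries were scaled on the oocyte transcripts and -0.11 when scaled on totals. The lower genes depended on this choice, with 1427 higher and 53 lower on oocyte transcripts and 1028 higher and 260 lower on totals. They also depended on single libraries: 14 and 26 were lower without control 5 hpf replicate 1 and replicate 2, 35 and 654 without control 7.5 hpf replicate 1 and replicate 2, and 20 and 18 without CHX replicate 1 and replicate 2.

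Endoderm and mesoderm genes were among those with the steepest rises. Of 28 measured endoderm genes, 20 rose (21 adjusted over the list alone) and 1 fell, vgll4.L (2 adjusted over the list alone). The homeobox gene bix1.3.S went from 14.5 ± 2.12 to 1938 ± 800 (SD, n = 2), a log2 fold change of 6.91 ± 0.31 (SE, adjusted p = 2.2e-06). mix1.L, a homeobox gene induced by nodal signalling that stands on both lists, went from 38.5 ± 4.95 to 2654 ± 1353 (log2 fold change 5.98 ± 0.32, adjusted p = 4.8e-06). The endoderm determinant sox17b.1.L rose by 3.88 ± 0.31 on the log2 scale. Of 39 mesoderm genes, 18 rose and none fell (27 and 0 adjusted over the list alone), among them the fibroblast growth factor gene fgf8.L (5.77 ± 0.41) and, at a smaller size, the maternally supplied T-box gene vegt.L (0.75 ± 0.14), whose call was lost without any library but control 7.5 hpf replicate 2 (adjusted p from 0.0522 to 0.0656). Of 13 nodal ligand genes, 8 rose (12 adjusted over the list alone), including nodal3.2.L (3.43 ± 0.52; adjusted p = 0.0553 without control 7.5 hpf replicate 1) and lefty.L, which was listed at 0 at 5 hpf and at 455 and 168 at 7.5 hpf.

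The dorsal organizer, the signalling centre of the gastrula, had the largest share of risen members, with 27 of 33 genes higher (29 adjusted over the list alone). The notochord homeobox gene not.S went from 44.0 ± 9.90 to 1641 ± 995 (log2 fold change 5.06 ± 0.38, adjusted p = 2.7e-05). The Wnt-driven homeobox gene sia1.L rose by 3.42 ± 0.64. The sia1.L call was lost without control 5 hpf replicate 2, control 7.5 hpf replicate 1 or either CHX library, with limma adjusted p from 0.0566 to 0.104. Of 59 ectoderm and neural genes, 29 rose and 1 fell, grhl1.L (36 and 1 adjusted over the list alone). The epidermal regulator grhl3.L moved from 0 to 671 and 244. Among 42 BMP pathway genes, 17 rose and 1 fell, smad7.L (21 and 5 adjusted over the list alone). Among 38 Notch pathway genes 15 rose (21 adjusted over the list alone), with hes7.2.L higher by 4.61 ± 0.38. Of 26 FGF and ERK feedback targets 8 rose and 1 fell, il17rd.L (11 and 1 adjusted over the list alone). Of 27 Wnt feedback targets 8 rose (9 adjusted over the list alone).

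Transcription factors tied to pluripotency and genome activation also rose in 22 of 44 cases, while myc.S fell (24 and 2 adjusted over the list alone). The POU factor gene pou5f3.2.S went from 289 ± 2.83 to 9199 ± 4988 (log2 fold change 4.87 ± 0.30, adjusted p = 9.1e-06). foxh1.2.L, which encodes a partner of Smad proteins, rose by 6.06 ± 0.34, and the homeobox gene ventx2.2.S by 4.92 ± 0.34. ventx1.2.L went from 0 to 549 and 262. Immediate early genes moved both ways, 11 up and 3 down of 62 (14 and 5 adjusted over the list alone): the phosphatase gene dusp1.S rose by 3.82 ± 0.39 and ier5.L by 2.59 ± 0.25, whereas ccn1.S, zfp36l2.1.S and myc.S fell. Of 37 stress-response genes 8 rose and 1 fell, dnajb9.S (9 and 1 adjusted over the list alone). The members that rose included the growth-arrest gene gadd45a.S (3.31 ± 0.52; adjusted p = 0.0743 without control 7.5 hpf replicate 1) and the cyclin-dependent kinase inhibitor cdknx.L (2.51 ± 0.37).

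Of 78 cell cycle genes 6 rose and 2 fell (6 and 4 adjusted over the list alone). The phosphatase gene cdc25b.L went from 13.5 ± 9.19 to 2428 ± 1551 and ccne2.L rose by 3.45 ± 0.47, while the mitotic kinase genes aurka.L and plk1.S fell. These 2, vgll4.L, grhl1.L, smad7.L, il17rd.L and myc.S were named after their values were seen. Splicing factor genes rose in 17 of 68 cases (25 adjusted over the list alone), with snrnp70.L, a component of the U1 particle, 2.65-fold higher (log2 fold change 1.40 ± 0.15) and hnrnpa2b1.L higher by 1.14 ± 0.17. Of 13 replication-dependent histone genes 5 rose (7 adjusted over the list alone), led by h4c4.L (2.00 ± 0.25) and h4c1.L (1.92 ± 0.31; adjusted p = 0.0506 without CHX replicate 2). Of 67 ribosome biogenesis genes 4 rose (4 adjusted over the list alone), including ncl.L (1.03 ± 0.16; adjusted p = 0.0654 without control 7.5 hpf replicate 1). Of 65 genes of the RNA polymerase II machinery, cdk9.L (2.28 ± 0.36) and taf7.L rose and ell.S fell (1 and 0 adjusted over the list alone). The cdk9.L call was lost without CHX replicate 1 or replicate 2 (adjusted p = 0.0533 and 0.0539). The ell.S and rpl13.L calls were lost without any library but control 7.5 hpf replicate 2, with adjusted p from 0.0855 to 0.195 and from 0.104 to 0.235. Both were lost with library weights (0.0539 and 0.0582), and rpl13.L with thinning (0.0853). Among 135 ribosomal protein genes rpl13.L alone was called and fell by 1.65 on the log2 scale (0 adjusted over the list alone; 8 had an unadjusted p under 0.05 in limma).

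mRNAs stored in the egg were made before EU was given, so their values here need not follow labelled RNA. Of 43 oocyte maternal transcripts none rose and 2 fell (0 and 0 adjusted over the list alone): zar2.S fell by 0.55 ± 0.13 and wee2.L fell by 0.54 ± 0.14 on the log2 scale. The wee2.L call was lost without any 1 of the 6 libraries (adjusted p from 0.0763 to 0.268), and the zar2.S call without any but control 7.5 hpf replicate 2 (0.0998 to 0.171). Both were lost with library weights (0.0533 and 0.07), and wee2.L with thinning (0.0685). The list median was -0.15, against 0.03 for all genes tested, and it turned to 0.03 when the libraries were scaled on this same list. The oocyte linker histone h1-8.S, the most abundant member, had values of 2503 and 2900 at 5 hpf and 2666 and 2669 at 7.5 hpf. Larger falls were found for smad4.1.S, a signal transducer of the TGF-beta family, which went from 7327 ± 1740 to 1976 ± 158 (log2 fold change -1.87 ± 0.20, adjusted p = 0.00028). The matricellular gene ccn1.S fell by 1.96 ± 0.32, the RNA-decay factor gene zfp36l2.1.S fell by 1.64 ± 0.22 and nfib.L fell by 3.48 ± 0.69. The ccn1.S call was lost without control 5 hpf replicate 1 (adjusted p = 0.0648), and the nfib.L call without either 5 hpf library, control 7.5 hpf replicate 1 or CHX replicate 1 (0.0505 to 0.148).

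Set tests of the 19 lists with measured members gave 14 with an adjusted p under 0.05 in camera at a preset correlation of 0.01, 13 of them upward and the oocyte list downward. None passed with an estimated correlation: its adjusted p was 0.165 for the nodal, organizer, mesoderm, endoderm, ectoderm, BMP, FGF, Wnt, Notch and splicing lists, 0.178 for the oocyte, pluripotency and histone lists, and 0.539 for the stress list. That test rests on the 3 residual degrees of freedom, so a list that fails it is not shown to be unchanged. The organizer list, with 27 of 33 members called, had an unadjusted camera p of 0.0578 there. The direction test fry passed 11 lists, with adjusted p between 0.0114 and 0.0210. For the cell cycle list the median (-0.04) and camera pointed down and the mean (0.23) and fry up, and for ribosomal proteins camera alone pointed down; neither list passed. The cell cycle median was 0.14 under scaling on oocyte transcripts, and the ribosomal protein median -0.06 under scaling on totals. The total of 1273 changed genes was 518 without control 7.5 hpf replicate 1, 2004 without control 7.5 hpf replicate 2, 804 without control 5 hpf replicate 1, and 575 and 559 without CHX replicate 1 and replicate 2, which enter only the estimate of the spread. With no filter on low genes it was 665, and of the named genes sia1.L, nfib.L, zar2.S, wee2.L, rpl13.L, ell.S and the histone gene h3c14.L lost their calls (adjusted p from 0.0586 to 0.122).

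**Figure D1:**
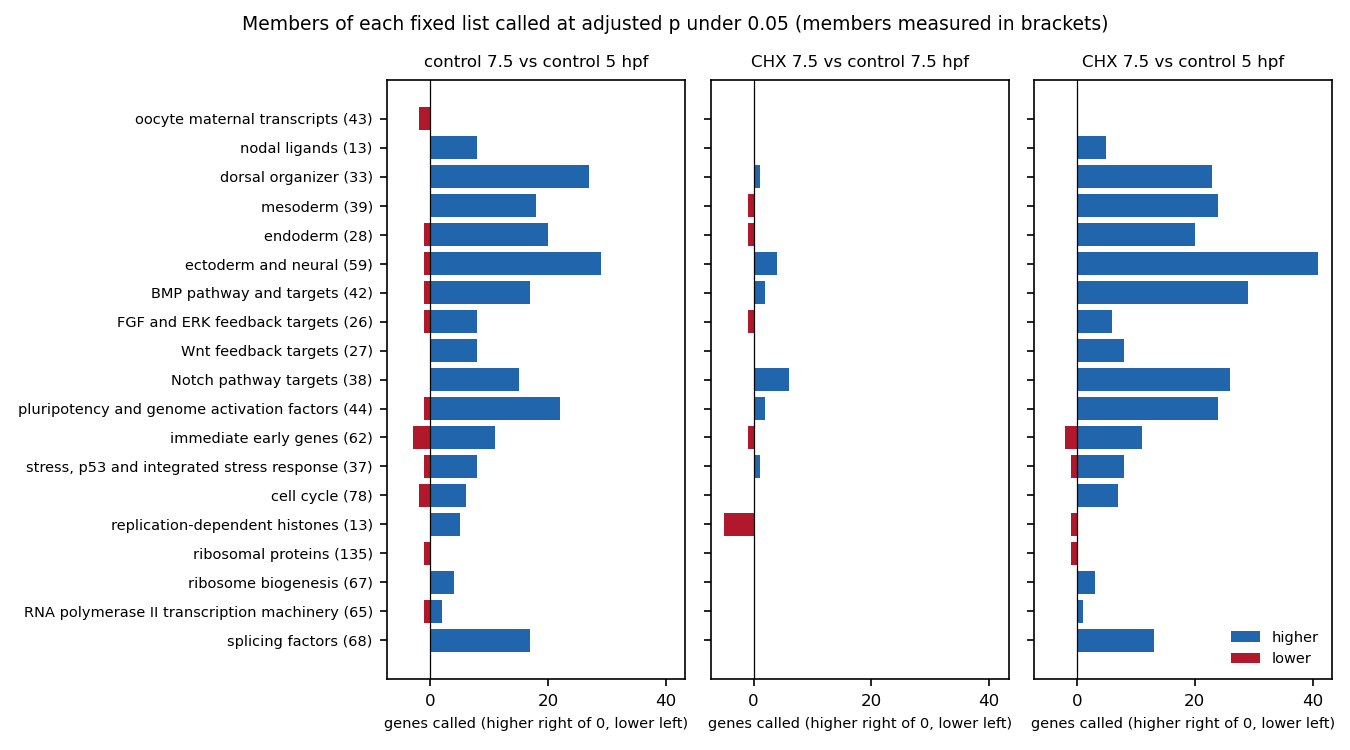
Genes called higher (blue, right of 0) or lower (red, left of 0) in each fixed gene list, as counts on the x axis, for the 3 comparisons; the number of members measured stands beside each list name. The dorsal organizer list had 27 of 33 members higher from 5 to 7.5 hpf in controls, and 5 of 13 histone genes were lower in CHX than in control embryos at 7.5 hpf.

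With translation blocked, histone genes such as h4c4.L lay below the level of controls at 7.5 hpf, and regulators such as neurog1.L, dlc.L and foxi1.S lay above it. Over all genes, 38 were higher and 67 lower in CHX than in control embryos of the same age, of which 35 and 61 by at least 2-fold (limma, adjusted p under 0.05). These counts, and which direction held more genes, depended on the settings: 23 higher and 49 lower at a pseudocount of 0.5, 108 and 111 at 5, 63 and 105 with the replicate number as a block, and 72 and 44 in a fit to the 2 groups alone. At an unadjusted p under 0.05 the number was 1581. Of the 67 lower genes, 57 had only a locus identifier and no gene symbol.

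Of 13 replication-dependent histone genes, 5 fell under CHX and none rose (9 and 0 adjusted over the list alone). The 5 became 0 with no filter on low genes, 4 at a pseudocount of 0.5, and 8 at a pseudocount of 5 or with the replicate number as a block. The count also changed when a library was left out, where a group holds a lone sample. h4c4.L was at 453 ± 93.3 in CHX embryos and 2977 ± 1213 in controls (log2 fold change -2.67 ± 0.25, adjusted p = 0.0038, n = 2), against 714 ± 38.9 at 5 hpf, from which it was not called different (log2 fold change -0.67 ± 0.25, adjusted p = 0.2). h4c1.L fell by 2.17 ± 0.31 and h3c14.L fell by 1.44 ± 0.21. h3c8.S was also called, and the most abundant, h2bc11.S, fell by 0.98 ± 0.18, from 73713 ± 11889 in controls to 37060 ± 2010. The median of the list was -1.30 and lay between -1.30 and -1.25 under each of the scalings tried, but the h2bc11.S call was lost under scaling on totals (adjusted p = 0.0613) and on trimmed means (0.0509), leaving 4 called histones. It was also lost with the strict filter (0.0662) and at a pseudocount of 0.5 (0.083). The variant histone gene h2ax.lS, which the list did not hold, fell by 1.34 ± 0.22. The calls of h3c8.S and h2bc11.S were lost without either 5 hpf library and that of h2ax.lS without control 5 hpf replicate 1 (adjusted p from 0.0524 to 0.0603). Histone copies are near-identical, and how the quantification divided their reads is not given in the sources used here, so the value of any single copy is uncertain. Outside the histones, mix1.L fell from 2654 ± 1353 in controls to 636 ± 127 (log2 fold change -1.97 ± 0.32, adjusted p = 0.026), the single call in the mesoderm and endoderm lists (1 lower, and 6 lower and 1 higher, adjusted over the list alone). Its adjusted p was 0.0539 without control 5 hpf replicate 1 and 0.0512 without replicate 2. The immediate early gene egr1.S, also an FGF target, was at 20.5 ± 14.9 against 205 ± 71.4 (log2 fold change -3.41 ± 0.62, adjusted p = 0.046), again the single call on each of its lists (1 lower on both adjusted over the list alone), and was lost without any 1 of the 6 libraries (adjusted p from 0.077 to 0.801), under scaling on totals (0.0539), at a pseudocount of 0.5 (0.0749), with library weights (0.0597) and with thinning (0.11).

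Transcripts above the control level were led by genes that were low or at 0 in controls at 7.5 hpf. The homeobox gene msx1.L was listed at 0 in both 7.5 hpf controls and at 637 and 418 under CHX. The zinc finger gene myt1.S (441 and 350), the multiciliated-cell regulators gmnc.L (304 and 221) and mcidas.L (248 and 166), the neural crest gene pax3.S (188 and 164) and the Notch target hes5.3.L (169 and 181) were likewise at 0 in both controls. The proneural gene neurog1.L stood at 2 and 17 in controls and at 1500 and 793 under CHX (log2 fold change 7.21 ± 1.01, adjusted p = 0.016). The single organizer gene called, otx2.S (3 higher and 3 lower adjusted over the list alone), stood at 15 and 6 against 810 and 551. The calls of pax3.S and hes5.3.L were lost without either 5 hpf library, that of mcidas.L without control 5 hpf replicate 1 and that of otx2.S without control 7.5 hpf replicate 2 (adjusted p from 0.051 to 0.0835). Those of gmnc.L, mcidas.L and pax3.S were lost with the strict filter (0.0661 to 0.0864). At a pseudocount of 0.5 these 3, hes5.3.L and otx2.S were lost (0.0605 to 0.0952), and hes5.3.L with thinning as well (0.0621).

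Of 38 Notch pathway genes 6 were higher and none lower (21 and 0 adjusted over the list alone). The 6 became 0 with no filter on low genes, and 3 and 10 at pseudocounts of 0.5 and 5. This count too changed when a library was left out. The ligand gene dlc.L was at 1507 ± 569 under CHX and 82.0 ± 21.2 in controls (log2 fold change 4.15 ± 0.55, adjusted p = 0.015), dll1.L was higher by 3.08 ± 0.53, and hes4.L by 2.49 ± 0.43. Of 59 ectoderm and neural genes 4 were higher (9 adjusted over the list alone), all from the placodal and epidermal families: foxi1.S by 4.53 ± 0.64, dlx5.L by 4.31 ± 0.65, dlx6.S by 4.29 ± 0.59 and dlx6.L. Both called BMP pathway genes of 42 were msx1 copies, msx1.L and msx1.S (16 adjusted over the list alone). The pluripotency list had klf5.L (1.18 ± 0.17) and klf5.S (0.79 ± 0.14) higher of 44 genes (5 higher and 1 lower adjusted over the list alone), and the stress list gadd45g.L (3.10 ± 0.56) of 37 (3 adjusted over the list alone). Without control 7.5 hpf replicate 2 the calls of dlc.L, dll1.L, hes4.L, dlx5.L, dlx6.S, dlx6.L, klf5.S and gadd45g.L were lost. Of the ectoderm and neural genes named here, only foxi1.S kept its call. The log2 fold changes of dlx5.L and dlx6.S were then 3.67 and 3.79. Those of hes4.L, klf5.S and gadd45g.L were also lost without either 5 hpf library (0.0512 to 0.077). At a pseudocount of 0.5 dll1.L, hes4.L, gadd45g.L and msx1.S were lost (0.0605 to 0.104), and gadd45g.L with thinning as well (0.0565). In the remaining 8 lists limma called no member. Unadjusted p-values under 0.05 were found there for 1 of 13 nodal ligand, 5 of 27 Wnt, 4 of 43 oocyte, 7 of 78 cell cycle, 6 of 135 ribosomal protein, 2 of 67 ribosome biogenesis, 5 of 65 polymerase and 7 of 68 splicing genes. Adjusted over the list alone, 1 nodal ligand gene was lower and no other member passed.

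In camera with the preset correlation, 6 lists passed: Notch (adjusted p = 1.5e-19), BMP (1.9e-11), ectoderm and neural (3.2e-08), pluripotency (0.034) and cell cycle (0.044) upward, and histones (1.8e-13) downward. With an estimated correlation none did, the adjusted p being 0.348 for Notch and histones, 0.414 for BMP and 0.636 for the other 3. No list passed fry, whose smallest adjusted p was 0.0831. Median, mean and tests did not share a sign for the FGF, Wnt, endoderm and polymerase lists, none of which passed. The number of calls changed with the libraries used, but a fit without 1 library leaves a lone sample in its group. Calls lost there may reflect low power alone. For h4c4.L the log2 fold change was -2.24 without control 7.5 hpf replicate 1, and -2.88 and -2.46 without CHX replicate 1 and replicate 2. For msx1.L it was 9.01, 8.71 and 9.32 in the same fits, and for egr1.S -3.05, -2.64 and -4.18. These values restate the single libraries and do not show why calls were lost. With no filter on low genes, none of the 105 calls was made (2318 genes at an unadjusted p under 0.05 in limma). The lower genes were 43 without control 5 hpf replicate 1, 45 without control 5 hpf replicate 2 and 45 under scaling on oocyte transcripts.

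**Figure D2:**
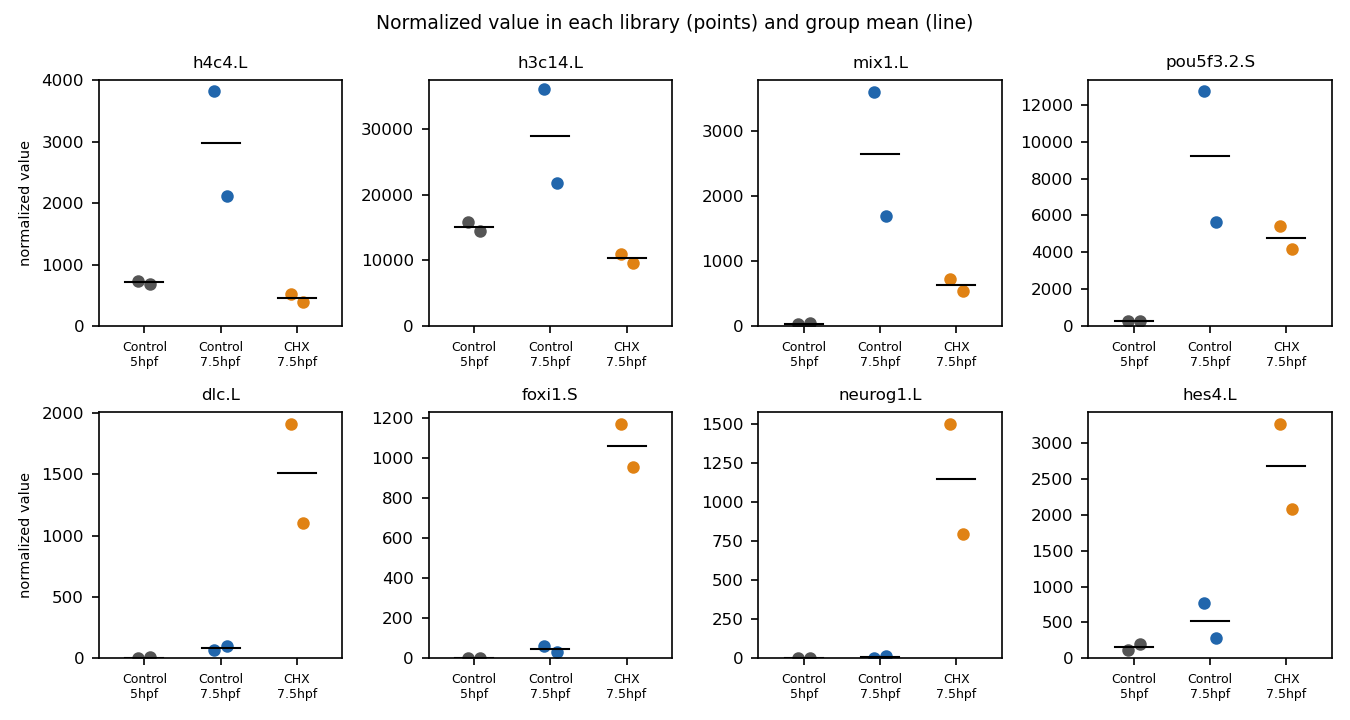
Normalized value (y axis, linear from 0) of 8 genes in each of the 6 libraries, with points for libraries and a line for each group mean. h4c4.L and h3c14.L in CHX embryos lay below both controls at 7.5 hpf, mix1.L was at 725 and 546 against 3610 and 1697, and dlc.L, foxi1.S, neurog1.L and hes4.L in CHX embryos lay above both controls.

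Against the common 5 hpf starting point, many developmental genes were higher in CHX embryos at 7.5 hpf, although no list passed camera with an estimated correlation (smallest adjusted p = 0.106). In this comparison 1106 genes were higher and 49 lower (limma, adjusted p under 0.05), 1021 and 24 of them by at least 2-fold, and 381 of the higher genes were listed at 0 at 5 hpf. Scaling on oocyte transcripts gave 1504 higher and 14 lower, and scaling on totals 1039 higher and 87 lower. id3.L was listed at 0 at 5 hpf and at 2124 and 1410 under CHX, the homeobox gene crx.S at 2167 and 1362, grhl3.L at 1449 and 1059, dlx5.L at 1219 and 1079 and foxi1.S at 1169 and 953, all from 0. hes7.2.L rose by 5.70 ± 0.38 on the log2 scale (adjusted p = 1.4e-05), not.S by 5.56 ± 0.38, ventx2.2.S by 5.45 ± 0.34, bix1.3.S by 5.49 ± 0.31, pou5f3.2.S by 4.04 ± 0.30 and sox17b.1.L by 3.58 ± 0.31, the last with an adjusted p of 0.0552 in limma without CHX replicate 1.

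Ectoderm and neural genes had 41 of 59 members higher (43 higher and 1 lower adjusted over the list alone), BMP pathway genes 29 of 42 (31), Notch pathway genes 26 of 38 (33), mesoderm genes 24 of 39 (32), organizer genes 23 of 33 (30), endoderm genes 20 of 28 (22 higher and 1 lower) and pluripotency factors 24 of 44 (27), where brackets give the count adjusted over the list alone. The Notch genes hes4.L and dlc.L rose by 4.09 ± 0.43 and 8.21 ± 0.55. Nodal ligand genes were higher in 5 of 13 cases (10), FGF targets in 6 of 26 (6) and Wnt targets in 8 of 27 (10), including axin2.L, a feedback inhibitor of the pathway, at 1.37 ± 0.28. Splicing factors were higher in 13 of 68 cases (22 higher and 1 lower), cell cycle genes in 7 of 78 (7 higher and 1 lower), ribosome biogenesis genes in 3 of 67 (2) and polymerase genes in 1 of 65 (1), cdk9.L. Immediate early genes were higher in 11 and lower in 2 of 62 cases (14 and 2), the latter ccn1.S and zfp36l2.1.S. Stress genes were higher in 8 and lower in 1 of 37 (11 and 1), with gadd45g.L up by 6.25 ± 0.56 and cdknx.L also called. Without CHX replicate 1 the calls of hes4.L, gadd45g.L, cdknx.L and axin2.L were lost, with adjusted p from 0.0593 to 0.377. That of axin2.L was also lost without either 5 hpf library or CHX replicate 2 (0.0844 to 0.108).

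No histone gene of 13 was called higher under CHX than at 5 hpf, and h3c8.S fell by 0.99 ± 0.21 (2 higher and 5 lower adjusted over the list alone; 7 had an unadjusted p under 0.05 in limma). rpl23.S was the single ribosomal protein gene called of 135 and fell by 1.02 ± 0.24 (0 adjusted over the list alone). No oocyte transcript of 43 was called in limma (0 adjusted over the list alone, 6 with an unadjusted p under 0.05). Among other genes, nfib.L fell by 3.61 ± 0.69, smad4.1.S fell by 1.46 ± 0.20, the retinoic acid receptor gene rara.S fell by 1.19 ± 0.24 and the chaperone gene dnajb9.S fell by 1.54 ± 0.36. Without CHX replicate 1 these calls and those of h3c8.S, rpl23.S and ccn1.S were lost, with adjusted p from 0.0899 to 0.276. All of these but smad4.1.S were also lost without control 5 hpf replicate 1 (0.138 to 0.328) and without CHX replicate 2 (0.143 to 0.317). The calls of nfib.L, dnajb9.S, h3c8.S and ccn1.S were lost without control 5 hpf replicate 2 (0.0514 to 0.188), and that of ccn1.S with thinning (0.0728). Camera with the preset correlation passed 16 lists. With an estimated correlation none passed, the adjusted p running from 0.106 to 0.536 over those 16, and fry passed 11, with adjusted p between 0.00422 and 0.0250. The total of 1155 was 70 without CHX replicate 1, 274 without CHX replicate 2 and 671 with no filter on low genes. With no filter the calls of axin2.L, nfib.L, dnajb9.S, h3c8.S, rpl23.S and ccn1.S were lost (adjusted p from 0.0519 to 0.119). The 49 lower genes were 9 and 13 without control 5 hpf replicate 1 and replicate 2, 78 and 76 without control 7.5 hpf replicate 1 and replicate 2, and 1 and 5 without CHX replicate 1 and replicate 2.

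Of the 1019 genes that rose at least 2-fold in controls, 771 (75.7%) were also called higher in CHX embryos against 5 hpf, and 247 were called in neither direction there. The comparison at 7.5 hpf, which also tests the difference between both changes, called 35 of the 1019 (3.43%) lower and 11 higher under CHX. Within lists, all 28 risen ectoderm and neural genes, all 15 Notch genes, all 17 BMP genes and all 21 pluripotency factors were also higher under CHX. The count was 21 of 27 for organizer genes, 19 of 20 for endoderm genes, 5 of 8 for nodal ligands and 0 of 3 for histone genes. The log2 difference between CHX and control at 7.5 hpf had a median of -0.40 over the risen genes (quartiles -1.24 and 0.40). Risen genes were selected on the same 7.5 hpf controls, which lowers this median with no effect of CHX. Among the 1720 genes at least 2-fold higher at an unadjusted p under 0.05 it was -0.36, and among genes so selected in simulated unchanged groups it was -0.92. The share of these genes lower under CHX at an unadjusted p under 0.05 was 13.8%, and 23.4% in the simulated groups. In those groups no gene truly rises, and 227 on average were so selected by noise alone. Selection lowers such genes more than genes with a true rise. The simulated values therefore cannot tell how much of the lower median selection accounts for. Within lists, under the same selection, the median was -0.98 for risen organizer genes, -1.13 for endoderm genes, 0.98 for ectoderm and neural genes and 1.67 for Notch genes. The BMP antagonist chrd.1.L was at 555 and 190 in controls and 47 and 39 under CHX (adjusted p = 0.29). The Wnt antagonist frzb.S was at 260 and 69 against 13 and 6 (adjusted p = 0.34), and neither was a call. pou5f3.2.S stood at 12726 and 5672 against 5402 and 4183 (adjusted p = 0.47).

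The changes with and without CHX shared the 5 hpf libraries, which alone gives some overlap. The lists of higher genes shared 815 members, where independent lists of these sizes would share 65.5. Simulated unchanged groups shared 0.08 on average over 100 draws. They had 2.95 calls on average over the comparisons together, so this overlap was bound to be small. At an unadjusted p under 0.05 in limma, 79.2% of the genes at least 2-fold higher in controls were also higher under CHX. In the simulated groups 22.8% were. Fold changes of the 2 comparisons correlated across genes with r = 0.80 (0.50 simulated), with a covariance of 1.85 against 0.22 simulated, a difference of 1.63. The controls could not be split, since each part would hold under 2 libraries, so part of the excess may come from the shared libraries. The size of the risen class changed with the libraries used. Of the risen genes, 67 of 546 were also higher under CHX without CHX replicate 1, 224 of 533 without CHX replicate 2, 416 of 452 without control 7.5 hpf replicate 1, 890 of 1238 without control 7.5 hpf replicate 2 and 452 of 608 with no filter on low genes.

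Of the 53 genes that fell at least 2-fold in controls, 12 were also lower in CHX embryos against 5 hpf and 41 were not called. smad4.1.S, ccn1.S and nfib.L were among the 12. Against controls at 7.5 hpf, 1 of the 53 was higher under CHX and none lower, and 50 had a positive difference, with a median of 0.65 on the log2 scale (quartiles 0.36 and 0.91). The 7.5 hpf controls enter both comparisons with opposite sign, and simulated unchanged groups gave a correlation of -0.50 between them, against an observed -0.32. The covariance over all genes tested was -0.46, against -0.22 simulated (-0.24 to -0.21 over the draws). The simulation gave every group the same spread per gene. Replicates of the 7.5 hpf controls spread most, with a log2 SD of 0.882 against 0.739 at 5 hpf and 0.572 under CHX. The simulated values may therefore understate what the shared controls give alone. They cannot tell whether the opposition goes beyond it. Neither the correlation nor the covariance covers the 53 genes alone. The 12 of 53 became 2 of 10 without control 5 hpf replicate 1, 4 of 21 without control 5 hpf replicate 2, 7 of 26 without control 7.5 hpf replicate 1, 14 of 529 without control 7.5 hpf replicate 2, 1 of 16 without CHX replicate 1, 2 of 17 without CHX replicate 2 and 3 of 22 with no filter on low genes.

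**Figure D3:**
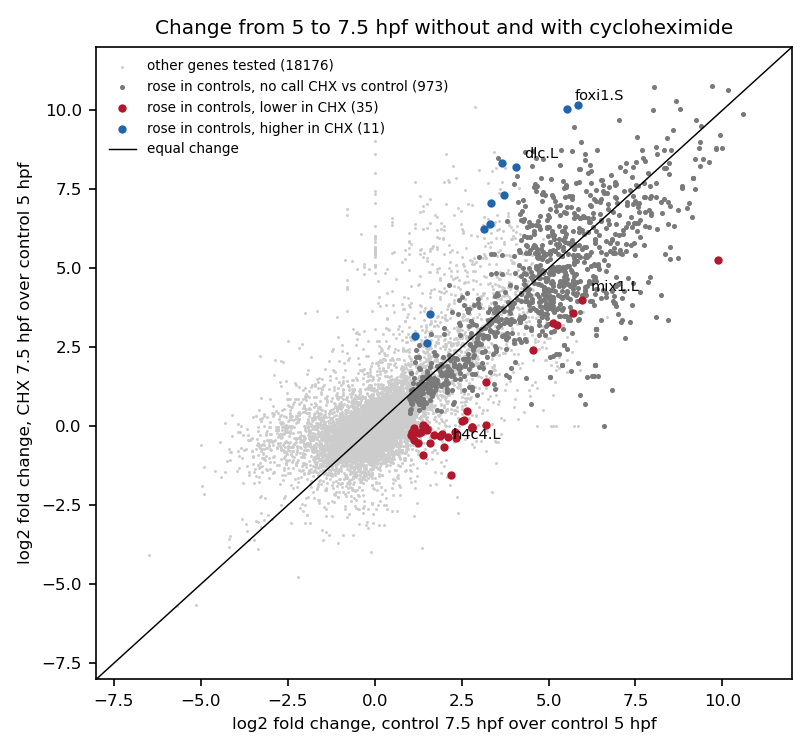
Log2 fold change from 5 to 7.5 hpf in control embryos (x axis) and from 5 hpf controls to CHX embryos at 7.5 hpf (y axis) for the 19195 genes tested, with a line of equal change. Of 1019 genes that rose in controls, 35 lower in CHX than in control embryos at 7.5 hpf (red) lie below the line and 11 higher (blue) above it; both axes share the 5 hpf libraries.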

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

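Trimmed-mean scaling, library weights and thinning were chosen after seeing the data; the other settings were planned. For 95 changes of named genes, not all of them printed, alternatives left 1263 values on their side of the threshold. They took 254 below it, raised 1 above it and changed the direction of none. The 1 was pou5f3.2.S in CHX against control, at -1.42 without control 7.5 hpf replicate 2 (adjusted p = 0.0287). Losses were most frequent without CHX replicate 1 (48), without CHX replicate 2 (43), with no filter (39) and without control 7.5 hpf replicate 1 (37). Of the list counts, 1562 stayed within 1.5 times and 358 moved further.

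With 1 library left out, calls ran from 518 (without control 7.5 hpf replicate 1) to 2004 (without replicate 2) for controls over time. They ran from 0 to 202 for CHX against control, and from 70 (without CHX replicate 1) to 1346 for CHX against 5 hpf. Risen genes also higher under CHX ran from 67 of 546 to 890 of 1238, and fallen genes also lower from 1 of 16 to 14 of 529. The 0 was met without control 7.5 hpf replicate 1 and without either CHX library, where limma gave 1482, 793 and 962 genes at an unadjusted p under 0.05. These fits have fewer samples, and a lone library is assumed to vary like the other groups.

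With no filter the counts were 665, 0 (2318 at an unadjusted p under 0.05 in limma) and 671 for the 3 comparisons, 452 of 608 for the risen and 3 of 22 for the fallen genes; the cause was not tested. A pseudocount of 5 gave 219 calls (108 higher and 111 lower) for CHX against control, a fit to the 2 groups alone 609 for controls over time, and library weights 20 of 36 fallen genes also lower under CHX; the causes were not tested. With the replicate number as a block, the calls were 1500, 168 (63 higher and 105 lower) and 1352. Samples with the same number deviated from their group means with correlations of 0.00617 and -0.0215 between 5 hpf and the 7.5 hpf groups, and 0.128 between control and CHX at 7.5 hpf. No label ties a number to shared material, so the plan used the number only as a block in this alternative. The value of 0.128 leaves pairing open for CHX against control at 7.5 hpf.

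Recomputed median-of-ratios scaling left 1273, 105 and 1156 calls, and thinning to the shallowest library 1205, 103 and 1122, of which 1138, 95 and 1058 were shared with the values as deposited. Depth limits low genes most at 5 hpf. A Wald test on counts and a count test on recovered reads were not run, because the values are not counts and whole reads were not recovered.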

Other observations

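The tests on histone genes, on the unnamed genes, on the replicates of the 7.5 hpf controls and on the share of new RNA in the CHX libraries were chosen only after the results were seen; those on thinning, on L and S copies and on genes at 0 were chosen before.

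The L and S copies that Xenopus laevis inherited from its ancestral species mostly moved together over the interval. Among genes called higher from 5 to 7.5 hpf whose other copy was tested, that copy had a positive fold change in 87.6% (432 of 493), against 52.2% of all genes, and was itself called in 55.6%. Of the pairs with a call, 137 were called in both copies, 137 in L alone and 82 in S alone (two-sided exact binomial p = 0.000246 for L against S). That test treats pairs as independent, and the levels of L and S copies were not matched. It does not show that L copies respond more often. Across the 4879 pairs the copies' fold changes correlated with r = 0.57 for controls over time, 0.42 for CHX against control and 0.72 for CHX against 5 hpf, where pairs are not independent replicates. Copies may share reads, which would raise these values.

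Risen genes listed at 0 at 5 hpf had a median log2 difference between CHX and control of -0.52, and those detected at 5 hpf -0.37. Within 3 strata of the control 7.5 hpf level, the medians of the 361 listed at 0 minus those of the 658 others were -0.46, -0.68 and -0.63 (mean -0.589, permutation p = 1e-04, the smallest that 10000 permutations over genes can give, and genes are not independent replicates). Both sets were chosen on the same 7.5 hpf controls, and a gene at 0 in the shallow 5 hpf libraries was undetected, not shown to be inactive.

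Of the 67 genes lower in CHX than in control at 7.5 hpf, 57 had no gene symbol. Of these, 78.9% had a place in the reference table, below the 80% set for a check of neighbours, so that check is void. As counts alone, 24 of the 45 with a place lay within 20 genes of a histone gene, against 50 of 2228 other unnamed genes tested.

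Histone genes lay below controls under CHX, with 5 of 13 called and a list median of -1.30. As a list they did not pass with an estimated correlation (adjusted p = 0.348) or in fry (0.190). A lower share of labelled RNA in the CHX libraries would lower new transcripts alike. The comparison used the 1373 other genes called higher in the 7.5 hpf libraries together than at 5 hpf, a choice that does not select on CHX against control. They had a median difference of -0.0704 (quartiles -0.72 and 0.76), averaged over control replicates that lay apart. Over 5 hpf these genes stood at a median of 4.63 and 3.60 in the controls and 4.57 and 3.86 under CHX. The histone list stood at 1.10 and 0.58 against -0.02 and -0.47. Both CHX libraries thus lay within the range of the controls for the 1373 genes and below both controls for the histone list. This argues against a lower share alone for the histone list. The sum over the list was lower by a log2 ratio of -1.14 (-1.47 without h2bc11.S), which reads moved between listed copies would not change. Reads shared with unlisted copies stay open, and no biological explanation was tested.

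The 7.5 hpf control replicates differed in the genes of the interval. Over 1106 genes called higher in CHX embryos against 5 hpf, a list that does not use these controls for its fold changes, replicate 1 exceeded replicate 2 by a median log2 difference of 0.959, with 912 genes (82.5%) positive. The difference over all genes was 0.03 and over the oocyte list -0.12. It was 0.990 over the 463 of these genes with a mean value of at least 200, where depth has little effect. That argues against the lower depth estimated for replicate 1. CHX replicate 1 also exceeded CHX replicate 2, by a median of 0.47 over the 1136 genes called higher in controls, so the shift is not particular to the controls. A larger share of newly made RNA in control replicate 1 could give this difference; slightly older embryos would too, and no test here separates age from capture.

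Notch pathway genes tended to stand above controls under CHX, with a list median of 1.96, 34 of 38 positive and 6 called. The ectoderm and neural list had a median of 0.59 and 4 of 59 called. Neither passed with an estimated correlation (adjusted p = 0.348 and 0.636), and the nodal ligand, organizer and endoderm lists, with medians of -0.68, -0.64 and -0.43, did not pass camera even at the preset correlation (0.0944, 0.0974 and 0.0579). A larger share of new RNA in the CHX libraries would raise new transcripts alike. The median difference of -0.0704 over the 1373 genes described above averages over control replicates that lay apart. Over 5 hpf both CHX libraries (4.57 and 3.86) lay within the range of the controls (4.63 and 3.60) for these genes. The Notch list stood at 5.75 and 4.89 under CHX, above both controls (3.05 and 1.82). For the Notch list this argues against a larger share alone. The ectoderm and neural list was not compared in this way. Thinning to the shallowest library kept 0.945 of the median of the 38 genes called higher (3.31 before, 3.13 after). Thinning keeps the expected ratio of genes detected well above 0 and started from estimated reads, so it cannot tell whether depth contributed. No biological explanation was tested.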
